A study of Mus musculus with 902 samples.

How the data were processed

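Bone marrow of C57BL/6 mice was the source of all samples. Per the labels, EILP were sorted as lineage-negative Kit+ 2B4+ α4β7+ Thy1- cells with expression from the Tcf7 reporter, from mice with 1 reporter allele for EILP and 2 for Tcf7KO EILP, and ILCP as the corresponding Thy1+ IL-7Rα+ cells. Single cells were digested with micrococcal nuclease in plates, amplified by PCR and size selected, per the labels' protocols. Of 902 samples, 832 single cells had files used here (331 EILP, 250 Tcf7KO EILP, 251 ILCP), and the 70 bulk samples were not analysed here. The submitters' processing notes name mm9, Bowtie2 and MACS2 without versions or roles.

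For each cell the authors deposited 2 lists of fragments by position, 1 with fragments of at most 80 bp (22 to 80 bp in the files) and 1 with fragments of 140 to 180 bp, with the length and a mapping quality of at least 11. The lists hold 17722862 short and 57203823 nucleosome-sized fragments in all, and no position occurs again within a cell's list. They are part of each library, so the ratio of short to nucleosome-sized fragments, not a library total, was used to describe digestion. Whether repeats had been removed by the authors is not given in the sources used here.

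The gene table gives values per Ensembl gene and library. They were read as deposited in CPM, reads scaled to a fixed library total, although the table's name says RPKM. The unit rests on the values. In each column 582 to 828 genes share 1 identical value, the most frequent one above 0, most low values are multiples of it, and the deposited columns sum to 910615 to 970667. Levels, floors and fold bounds depend on this reading. The design had assumed RPKM, and the test on the log scale was kept. With the step taken as 1 read, the libraries held an estimated 11286000, 10007300 and 16959800 (WT1 to WT3) and 12562100, 12151200 and 11507400 (KO1 to KO3) reads. Of the values under 30 steps, 78.6 to 85.6% were whole within 0.01, too few for whole reads to be recovered, so no count test was run. No label describes the libraries behind this table. They were read as RNA expression from the gene identifiers and values, and their columns were assigned to WT and KO by name. Nothing says that the 3 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical. The aligner, counter and annotation of this table are not given in the sources used here. Symbols were matched for 17118 of 17165 identifiers (12147 with the version). The reference tables are of another build (GRCm38.p6), so no gene coordinates are given and fragments were not assigned to genes. The gene-wise accessibility comparisons planned for the lists were therefore not run.

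Genes of at least 1 CPM in any library (12892) were tested with limma 3.58.1 (R 4.3.3) on log2(CPM + 1), KO against WT, 6 libraries in 1 fit, with Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(CPM + 1) scale, which understates the change of low genes. Bounds for genes listed at 0 used 3 reads per library, 0.248 CPM on average. The 13 gene lists (179 genes in all), namely ILC precursor, ILC2, ILC3 and LTi, ILC1 and NK, T lineage, B lineage, dendritic cell, myeloid, stem and multipotent progenitor, erythroid and megakaryocyte, Wnt pathway and TCF1 targets, housekeeping, and silent in blood, were fixed before the data were examined and tested with camera (preset correlation 0.01, and estimated) and fry, and adjusted together. The genes named by rule were Tcf7, list members past the threshold, and the 5 largest rises and 5 largest falls past it (4 fell). List members named without passing over all genes (Spib, S100a8 and Ccr6 among them), the other called genes, the neutrophil and Y-linked genes, and Xist were chosen after their values were seen. A called gene is not reported here. On data simulated for this comparison (12892 genes, 200 changed) limma recovered 0% of genes changed by 2, 23.5% of those changed by 3 and 66.0% of those changed by 4 on the log2 scale, with at most 6% false calls, and made 0 calls with none changed.

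Fragments were assigned to positions by their midpoints in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Windows of 1000 bp, or bins of 200 bp in region calling, with over 2 fragments per covering cell were left out as pile-ups, a choice made after seeing the data (53 windows with 1.06% of nucleosome-sized fragments, 160 windows with 2.21% of short fragments, and 2612 bins). Accessible regions were called once from all cells, in bins of 200 bp with a Poisson p under 1e-05 against the larger of the genome mean and the surrounding 10 kb, with neighbouring bins merged. Regions were compared at matched fragment totals after adding 1 to each count, beside a split of EILP blocks into 2 sets. On simulated counts with no region changed, 33.8% of regions were at least 2-fold apart, the share that counting alone gave there. The simulated counts were somewhat above the matched EILP counts and alike in both arms, so this share is not an exact floor for the data. Regions were named by rule when they held at least 100 fragments in both groups together and were at least 1.5-fold apart, up to 5 each way. Spacing is the slope of peak positions in the distances under 1200 bp between nucleosome-sized fragments of a cell, smoothed with an SD of 15 bp, and simulated spacings of 180, 190 and 200 bp were recovered as 180.1, 189.9 and 199.7 bp. Occupancy around regions under 50 fragments was taken within 40 bp of the centre and at 80 to 140 bp, relative to 800 to 1000 bp away. For similarity, cells were thinned to the 10th percentile of short fragments and shallower cells left out. Clusters came from latent semantic indexing (30 components without the first, scikit-learn 1.9.0), 15 neighbours and the Leiden algorithm at resolution 1 (leidenalg 0.10.2, igraph 0.11.9), with no caller for doublets.

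Each cell is a sample in the series and no label names its animal, so each population is 1 sample. Shares have exact 95% binomial intervals and folds exact conditional ones. Since PCR fragments without molecular identifiers are not independent molecules, these cover counting error only. Blocks of 96 consecutive library numbers were used as possible plates, which the labels do not state. Alternatives were a pseudocount of 0.1, no filter, a replicate block, each library left out, a stricter region threshold, other scalings, thinning, shared blocks, a 1.5-fold limit, other fragment lengths, each block left out, and a lower resolution. Further ones were added after seeing the data, namely a trend in limma, quantile normalisation, the number of genes detected as a covariate, libraries without Y-linked transcripts, autosomes only, regions by fragment number, and pile-ups kept. Figures were drawn with matplotlib 3.10.9.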

Results

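The series was used to examine TCF1, the transcription factor encoded by Tcf7, in early innate lymphoid progenitors (EILP), bone marrow cells that give rise to innate lymphoid cells and are the first of that lineage to express TCF1. Single-cell micrococcal nuclease sequencing (scMNase-seq) had been applied to cells sorted from the bone marrow of C57BL/6 mice. Micrococcal nuclease cuts DNA that is not protected by protein, so short fragments mark accessible DNA and fragments of nucleosome length mark nucleosomes. Files for 832 cells were used. They comprised 331 EILP cells and 250 EILP cells from mice with both Tcf7 alleles disrupted (Tcf7KO EILP). The rest were innate lymphoid cell precursors (ILCP), a later stage marked by surface Thy1 and IL-7Rα. Per the labels, the EILP cells came from mice heterozygous for the Tcf7 reporter allele that Tcf7KO EILP carried on both copies. Tcf7KO EILP were therefore not set against wild-type cells. A gene table with 3 EILP libraries labelled WT and 3 labelled KO was also used. Whether the libraries labelled WT came from mice with the reporter allele is not given in the sources used here. The other 70 samples of the series, bulk profiles of chromatin marks, TCF1 and DNase I, were not analysed here.

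The gene table was used to ask how EILP expression differed with the Tcf7 genotype. Its values were read as CPM, read counts scaled to the library total, from the values themselves, and the libraries held an estimated 10007300 to 16959800 reads. Tcf7 (ENSMUSG00000000782.15) itself stood at 1074 ± 176.5 CPM in the libraries labelled WT and 1134.3 ± 7.53 CPM in those labelled KO (mean ± SD, n = 3 each), a log2 fold change of 0.09 (SE 0.32, limma adjusted p = 0.961). The labels of the cells name an EGFP null allele, and transcript of Tcf7 was counted at a similar level in both groups, so its level does not check the labels. Directions between these libraries rest on the labels KO and WT.

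Between the libraries labelled KO and WT, 22 of 12892 tested genes passed, 18 of them higher and 4 lower in KO (limma, Benjamini-Hochberg adjusted p from 0.0299 to 0.0459). The 18 genes that rose were near silent in the libraries labelled WT, with means of at most 0.543 CPM, and stood at means of 11.8 to 39.2 CPM in those labelled KO. Itgam (ENSMUSG00000030786.18), which encodes the CD11b integrin chain of myeloid cells, rose from 0.0393 ± 0.0681 to 20.4 ± 6.33 CPM (log2 fold change 4.32, SE 0.36, limma adjusted p = 0.0299, n = 3). C3 (ENSMUSG00000024164.15), the central complement component, rose from 0.151 ± 0.0445 to 39.2 ± 10.3 CPM, the largest rise on the log2 scale at 5.09. Clec7a, the β-glucan receptor dectin-1 of myeloid cells, rose to 13.7 ± 4.38 CPM. Blk, a Src-family kinase of B cells, rose from 0.0333 ± 0.0577 to 12.3 ± 2.21 CPM (log2 fold change 3.67), and Rel, an NF-κB subunit, rose to 13.1 ± 1.12 CPM.

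Mtmr10 (ENSMUSG00000030522.14), a myotubularin-related gene, was listed at 0 in the 3 libraries labelled WT and reached 33.5 ± 13.6 CPM in those labelled KO, at least 135-fold higher when set against a floor of 3 reads per library. Akap17b (ENSMUSG00000059708.12) was likewise listed at 0 in WT and reached 17.0 ± 2.99 CPM, at least 68.5-fold higher, and Sema3d and Hid1 were also listed at 0 there. Zfp41 (ENSMUSG00000047003.14), a zinc finger gene, rose from 0.157 ± 0.180 to 24.0 ± 10.8 CPM. Other genes that rose were Zfp160, Pard6a, Sema3d, Sdc4, Taok1, Pik3c2a, Exoc3l, Hid1 and Etfbkmt, with log2 fold changes between 3.33 (Etfbkmt) and 4.12 (Zfp160 and Pard6a). The 4 genes that fell were Zranb3 (ENSMUSG00000036086.16), which encodes a DNA annealing helicase, Prpf40b (ENSMUSG00000023007.15), a splicing factor gene, Dmwd (ENSMUSG00000030410.16) and Kif13a (ENSMUSG00000021375.9), a kinesin gene. Zranb3 went from 34.4 ± 8.96 to 0.0564 ± 0.0489 CPM (log2 fold change -5.03) and Dmwd from 17.0 ± 4.66 to 0.0869 ± 0.151 CPM (-4.02). Prpf40b (22.0 ± 4.46 CPM in WT) and Kif13a (14.5 ± 2.52 CPM in WT) were listed at 0 in all libraries labelled KO, at least 88.5-fold and 58.3-fold lower.

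The 22 calls were close to the threshold, and their number moved with the settings. A replicate block left 0 calls, as did a trend in limma, the latter added after seeing the data. Split as WT1, WT2 and KO3 against the rest, the same 6 libraries gave 67 calls. A count of 22 therefore does not by itself set the labels KO and WT apart from other groupings. With a pseudocount of 0.1 limma gave 52 calls, 46 higher and 6 lower, of which 16 were among the 22, and with no filter 30, of which 20 were. After quantile normalisation, an alternative added after seeing the data, limma gave 5 calls, 2 higher and 3 lower. Leaving out any 1 of the 6 libraries left 0 calls by limma, with 4.93 to 7.30% of genes at an unadjusted p under 0.05 against 5.31% (684 genes) with all libraries. The groups did not overlap for any of the 22 genes, and over all genes tested the groups were apart for 11.7%, where chance gives 10%. A fit with the number of genes detected as a covariate gave 0 calls and 649 genes at an unadjusted p under 0.05, with all 22 log2 fold changes of the same sign. Genes with any read numbered 11340, 11360 and 12389 in the libraries labelled WT and 12259, 12909 and 11744 in those labelled KO. Y-linked transcripts (Ddx3y, Eif2s3y, Kdm5d and Uty) summed to 112 CPM in KO1 and 75.1 CPM in KO3 but to 0.247 CPM in KO2 and at most 0.200 CPM in WT. The X-linked transcript Xist stood at 48.9, 46.9 and 13.5 CPM in KO1 to KO3 and at 28.2 to 80.4 CPM in WT. KO1 and KO3 thus held both, and Y-linked transcripts alone do not settle the sex of their donors.

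**Figure D1:**
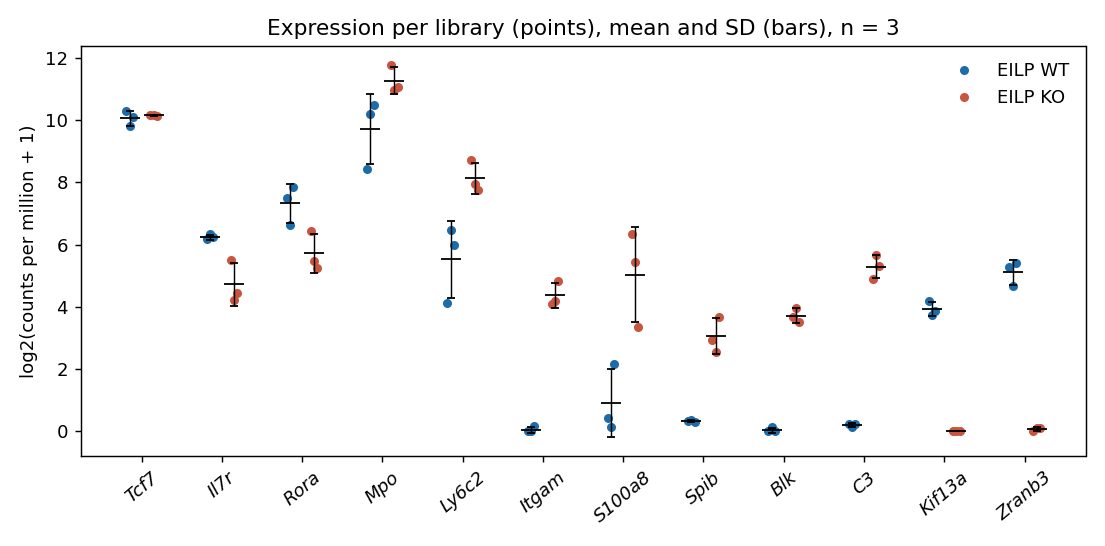
Expression of 12 genes as log2(CPM + 1) on the vertical axis, with 1 point per library, 3 libraries per group, and the mean and SD as bars. Tcf7 stood at a similar level in both groups, Itgam, Blk and C3 were near 0 in each library labelled WT, and Kif13a was at 0 in each library labelled KO.

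Genes of the myeloid list stood higher in the libraries labelled KO. Of 16 tested members 15 had a higher mean log2 value, with a median log2 fold change of 1.82, and the list stood apart from other genes (camera, preset correlation, adjusted p = 2.09e-05; adjusted p = 0.241 with an estimated correlation). Over all genes tested 54.9% had a higher mean log2 value, and 62.9% of those with a mean log2 value of 0 to 2. Of the list only Itgam passed over all genes tested. Adjusted over the list alone, Itgam and S100a8 passed, the latter a gene of neutrophils and monocytes at 1.31 ± 1.88 CPM in WT and 43.6 ± 35.1 CPM in KO (adjusted p = 0.0378 over the list, limma). Other members did not pass by themselves. Mpo, the granule enzyme myeloperoxidase, stood at 988.5 ± 575 CPM in WT and a mean of 2552 CPM in KO (log2 fold change 1.56, SE 0.64), and Ly6c2, a surface antigen of monocytes, at 55.7 ± 36.4 and 292.7 ± 107.4 CPM. Prtn3, a granule protease, stood at 85.8 ± 31.8 and 286.2 ± 135 CPM, and Csf1r, the macrophage growth factor receptor, at 8.12 ± 13.2 and 37.5 ± 9.78 CPM. Spi1 alone had a lower mean (129 ± 37.1 and 105.2 ± 24.2 CPM). The groups did not overlap for 7 of the 16 members, Mpo, Ly6c2, Prtn3 and Csf1r included, and for 11.7% of all genes tested. Csf3r, Csf2ra and Cebpb rose little (log2 fold changes 0.19, 0.26 and 0.32). Elane overlapped, at 0.0886, 42.7 and 184.8 CPM in WT1 to WT3 and 1032, 326.4 and 137.7 CPM in KO1 to KO3. S100a8 stood at 79.4, 42.3 and 9.12 CPM in KO1 to KO3. For 5 other genes abundant in mature neutrophils, chosen after the values were seen (S100a9, Ngp, Camp, Ltf and Fcnb), the median of the KO means was 0.658 CPM and the highest 1.40 CPM. Among the 4 libraries without Y-linked transcripts, of which KO2 alone is labelled KO, the adjusted p of the myeloid list was 0.00319 (camera, preset correlation), and over its alternatives with at least 2 libraries per group it ran from 1.63e-06 to 0.00293.

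Genes of the dendritic cell list were also higher, 15 of 16 tested, with a median log2 fold change of 1.01 (camera adjusted p = 0.000547; adjusted p = 0.241 with an estimated correlation). The median was 1.10 with the 2 members listed at 0 in WT at their bounds. No member passed over all genes. Adjusted over the list alone Spib passed, a factor of plasmacytoid dendritic and B cells (0.267 ± 0.0320 and 7.79 ± 3.61 CPM, adjusted p = 0.00853 over the list, limma). Flt3, a cytokine receptor of progenitors and dendritic cells, stood at 113 ± 4.02 and 213.0 ± 38.5 CPM, and Cd74, which encodes the MHC class II invariant chain, at 215.8 ± 49.3 and 671.8 ± 416.3 CPM. Irf8 was the exception (565 ± 142.5 and 498 ± 142.4 CPM). The dendritic cell call was lost without library WT3 (camera adjusted p = 0.0762, against 6.52e-05 to 0.00354 under its other alternatives).

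The lists of the innate lymphoid lineage did not pass in camera. In the ILC precursor list 11 of 18 tested genes were higher (median log2 fold change 0.28, camera adjusted p = 0.891). Il7r, the IL-7 receptor chain, stood at 74.8 ± 4.14 CPM in WT and 27.6 ± 14.7 CPM in KO (log2 fold change -1.52, SE 0.44, limma adjusted p = 0.681). Rora, a nuclear receptor needed for ILC2, stood at 179, 98.9 and 231.7 CPM in WT1 to WT3 and 85.6, 43.4 and 37.0 CPM in KO1 to KO3 (log2 fold change -1.61, limma adjusted p = 0.785). Zbtb16, which encodes PLZF, stood at 35.1 ± 26.8 and 76.3 ± 3.29 CPM. Id2 (871.6 ± 156.0 and 698.9 ± 112 CPM), Gata3 (219.12 ± 37.2 and 288.7 ± 63.1 CPM), Tox (342 ± 31.5 and 434.4 ± 38.4 CPM) and Nfil3 (336.7 ± 16.6 and 399.8 ± 40.0 CPM) had log2 fold changes from -0.32 (Id2) to 0.39 (Gata3), and none passed. The ILC2 list had 3 of 8 tested genes higher (median log2 fold change -0.09 and mean 0.02, which differ in sign, camera adjusted p = 0.790). The ILC3 and LTi list had 6 of 8 higher (median 0.65, camera adjusted p = 0.0856), and Ccr6 passed over the list alone (adjusted p = 0.0462, limma), listed at 0 in WT and at 10.4 ± 9.58 CPM in KO. The ILC1 and NK list had 10 of 13 higher (median 0.37, camera adjusted p = 0.0856), including Eomes, a T-box factor of natural killer cells (26.8 ± 6.71 and 90.1 ± 38.0 CPM), and Klrd1 (57.4 ± 55.3 and 166 ± 79.3 CPM). Without library WT1 its camera adjusted p was 0.00211, in a range of 0.00211 to 0.565 over its alternatives.

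Lists of other lineages gave the following. The B lineage list had 5 of 6 tested genes higher (median log2 fold change 0.76, camera adjusted p = 0.0511), with Blk the called member. Its camera adjusted p was 0.0226 without WT2 and 0.0145 without KO2, in a range of 0.0104 to 0.260 over its alternatives. The T lineage list had 10 of 17 higher (median 0.03, camera adjusted p = 0.891), with a mean of 0.28 although camera placed it downward. Zap70, a kinase of T cell receptor signalling, stood at 3.37 ± 5.53 and 21.2 ± 6.49 CPM. The stem and multipotent progenitor list had 10 of 13 higher (median 0.39, camera adjusted p = 0.0667, and 0.0268 after quantile normalisation in a range of 0.0268 to 0.205 over its alternatives), among them Hlf (1.36 ± 2.35 and 15.6 ± 10.1 CPM) and Lmo2 (10.6 ± 3.83 and 26.0 ± 6.17 CPM), and none of its genes passed. The erythroid and megakaryocyte list had 8 of 8 higher (median 1.43, camera adjusted p = 0.0667), with adjusted p of 0.0183 without WT2 and 0.0282 without KO2, in a range of 0.0183 to 0.901 over its alternatives. Its Hba-a1 values of 674 CPM in KO1 and 81.1 CPM in KO3 stood beside 0.908 CPM in KO2 and at most 22.1 CPM in WT. The list of Wnt pathway and TCF1 target genes had 6 of 10 higher (median 0.21, camera adjusted p = 0.790), with Lef1 at 29.6 ± 36.3 and 60.0 ± 42.8 CPM and Myc at 344.8 ± 59.7 and 313.6 ± 32.9 CPM. Housekeeping genes showed 8 of 16 higher (median -0.05, camera adjusted p = 0.489). Of the list silent in blood 7 genes were in the table and none reached 1 CPM. For a rotation test of whether each list moved on balance one way (fry), the adjusted p was 0.0256 for the B lineage, dendritic cell and ILC3 lists and 0.0276 for the myeloid list. No list passed in camera with an estimated correlation. Each median was also set against 10000 random lists of equal size, matched on mean level. Random medians lay below it in 100% for the myeloid, 99.99% for the dendritic cell and 99.6% for the erythroid list. Shares were 89.0% for B lineage, 88.9% for ILC3, 87.0% for stem cell and 78.25% for ILC1 and NK genes. They were 96.9% for ILC precursor and 93.8% for housekeeping genes, and 19.8 to 64% for the ILC2, T lineage and Wnt lists.

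**Figure D2:**
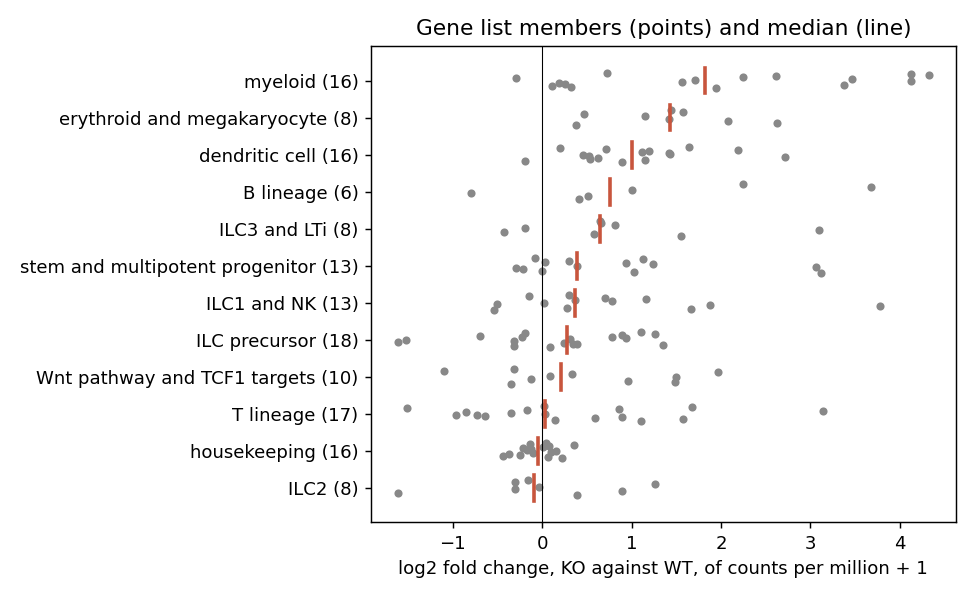
Log2 fold change, libraries labelled KO against those labelled WT, of the tested members of 12 gene lists (points, number tested in brackets) with the list median as a line. The myeloid median was 1.82 and the housekeeping median -0.05.

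The single-cell data were used to ask how accessibility, nucleosome positions and cell-to-cell similarity differed between EILP, Tcf7KO EILP and ILCP. No label names the animal of a cell, so each population counts as 1 sample, no test across cells was run, and intervals cover counting error only. Cells were grouped by library number into blocks of 96 consecutive numbers, taken as a stand-in for plates. EILP and Tcf7KO EILP cells shared 4 blocks, and EILP and ILCP cells shared 2. A median of 17469 short fragments (at most 80 bp; interquartile range 11614 to 26338) was recorded per EILP cell, 17411 (10868 to 29819) per Tcf7KO EILP cell and 10811 (6979 to 18334) per ILCP cell. The medians for nucleosome-sized fragments (140 to 180 bp) were 65822, 73529 and 48756. The median ratio of short to nucleosome-sized fragments was 0.274 in EILP, 0.254 in Tcf7KO EILP and 0.220 in ILCP, within block medians that ran from 0.193 to 0.483, 0.216 to 0.276 and 0.171 to 0.415, so the populations differed by less than their blocks did.

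Nucleosome spacing was alike in the 3 populations once pile-ups of fragments, 1.06% of the nucleosome-sized ones, were left out, a choice made after seeing the data. The distance between nucleosome centres in the same cell grew by 191.3 bp per nucleosome in EILP (SD over 7 blocks 0.871 bp), 191.0 bp in Tcf7KO EILP (SD over 7 blocks 0.692 bp) and 190.9 bp in ILCP (SD over 5 blocks 1.13 bp). These values differed by less than the blocks of 1 population, which ranged from 190.5 to 192.7 bp in EILP. With the pile-ups kept the slopes were 197.9 bp in EILP, 184.08 bp in Tcf7KO EILP and 198.6 bp in ILCP. They came from 8, 8 and 9 peaks in place of 6, and in EILP from 23831997 pairs of fragments in place of 1437598. Most pairs thus involved a pile-up, and these slopes are not read as nucleosome spacing. With all cells thinned to the same number of fragments the values were 190.3, 193.8 and 192.5 bp. The likeness therefore holds for the data without pile-ups at full depth. At 21478 accessible regions, nucleosome-sized fragments were depleted at the centre relative to the flanking nucleosomes. The flanking positions stood at 1.37 times the level 800 to 1000 bp away in EILP, 1.40 in Tcf7KO EILP and 1.42 in ILCP, and the centre at 1.06, 1.05 and 1.08. The ratio of centre to flank was 0.779 in EILP, 0.750 in Tcf7KO EILP and 0.759 in ILCP, with block ranges of 0.735 to 0.812, 0.705 to 0.789 and 0.732 to 0.790. Short fragments at the centre stood at 9.72, 8.27 and 10.5 times the distant level, with block ranges of 7.06 to 11.6, 6.97 to 11.2 and 9.41 to 11.8. The regions were called from these same short fragments, so a central peak of them is given by the selection.

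**Figure D3:**
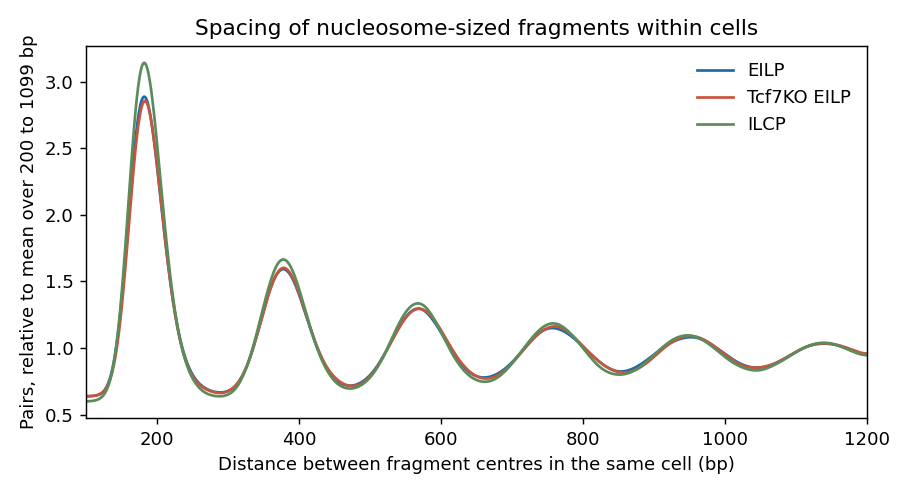
Distances between centres of nucleosome-sized fragments in the same cell, in bp, against the number of pairs relative to their mean, pooled over the cells of each population. The peaks recur every 191.3 bp in EILP, 191.0 bp in Tcf7KO EILP and 190.9 bp in ILCP.

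**Figure D4:**
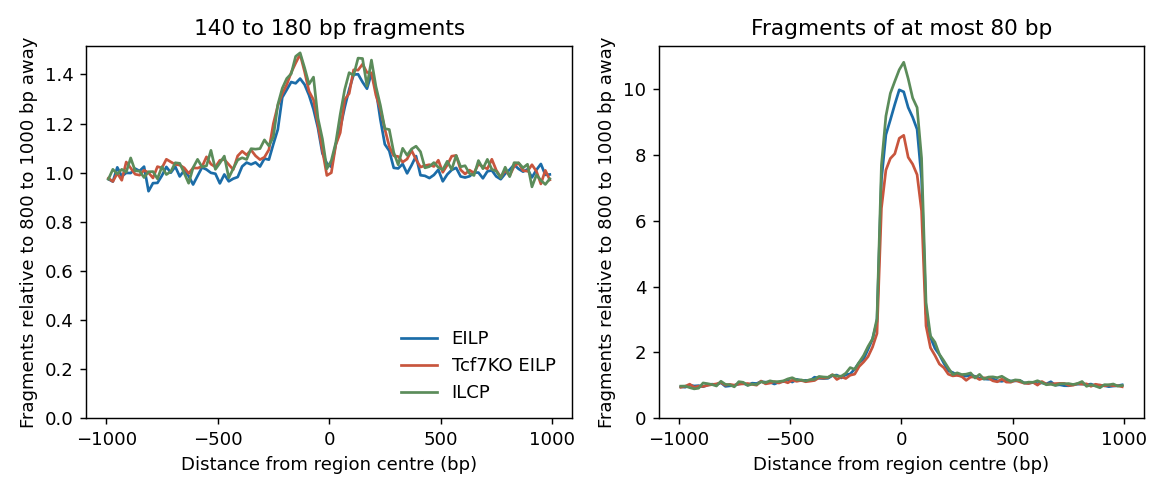
Nucleosome-sized fragments (left) and short fragments (right) by distance in bp from the centres of 21478 accessible regions, relative to 800 to 1000 bp away, for each population. Nucleosome-sized fragments at the flanks stood at 1.37 (EILP), 1.40 (Tcf7KO EILP) and 1.42 (ILCP). The central peak of short fragments is given by the selection of regions from them.

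Accessible regions called from all cells together numbered 21904, with a median of 13 short fragments each, and held 2.22% of the short fragments of EILP (exact 95% interval 2.21 to 2.24), 1.86% of those of Tcf7KO EILP (1.85 to 1.87) and 2.43% of those of ILCP (2.42 to 2.45). Single blocks spanned 1.76 to 2.74%, 1.43 to 2.47% and 2.06 to 2.86%, so these shares were not separable from the spread between blocks. At 3579846 matched fragments, 41.8% of regions were at least 2-fold apart between Tcf7KO EILP and EILP (exact 95% interval 41.2 to 42.5%), against 41.3% between 2 sets of EILP blocks. Of all regions 13.6% were higher and 28.2% lower in Tcf7KO EILP, which became 17.9% and 22.2% when scaled to the fragments inside regions, and the EILP sets gave 15.0% and 26.3%. Between ILCP and EILP 39.2% were apart (38.6 to 39.9%), against 41.2% between the EILP sets. Over 22 splits of the EILP blocks the share ran from 39.7 to 43.4%, and these shares are mostly counting noise. On simulated counts, changing 200 regions 4-fold moved the share from 33.8 to 33.9%, so a like share does not show that the populations were alike. Autosomal regions under 50 fragments were ranked by fold in the blocks that the 2 populations compared did not share. In the shared blocks, the top 5% for Tcf7KO EILP stood at 1.05-fold of EILP (0.996 to 1.12) and those for ILCP at 0.972-fold (0.872 to 1.08). The lowest 5% stood at 0.998-fold (0.939 to 1.06) and 0.911-fold (0.807 to 1.03). At this depth a difference in accessibility at most single regions was not detectable.

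Among regions with at least 100 fragments, 11 were at least 1.5-fold higher and 2 lower in Tcf7KO EILP with the same direction in shared and other blocks. Coordinates are those of the files, for which the submitters' notes name mm9, and genes at these positions were not analysed here. The region at chromosome 17, 36621601 to 36622000, was 14.01-fold higher (6.84 to 33.3), with 8 short fragments in EILP, and the one at chromosome X, 121307201 to 121307600, held 14 in EILP (9.03-fold, 5.17 to 17.0). Nucleosome-sized fragments were also higher there, 57.0-fold in the first region (19.1 to 279.7, with 3 in EILP) and 28.0-fold in the second (16.7 to 50.6, with 15 in EILP), so these are not rises of short fragments alone. The next were on chromosome 17 at 63086801 to 63087000 (2.11-fold, 1.65 to 2.71) and on chromosome 9 at 3002401 to 3002600 (1.84-fold, 1.47 to 2.31) and 3032001 to 3032200 (1.77-fold, 1.26 to 2.49). Within 1000 bp of these 5 regions, fragments of the 17 Tcf7KO EILP cells with a Y share under 0.05% were set against the number expected from the depth of those cells. Nucleosome-sized fragments numbered 1 against 24.8 at the region on X, 1 against 3.51 at 36621601 and 0 against 0.570 at 63086801 on chromosome 17, and 26 against 35.2 and 25 against 33.3 at the 2 on chromosome 9. Short fragments in the same order numbered 0 against 4.32, 0 against 1.56, 0 against 2.93, 21 against 21.4 and 8 against 8.51. The nucleosome-sized numbers expected on X (24.8) and at the 2 on chromosome 9 (35.2 and 33.3) were far above the 0.570 at 63086801. Nucleosome-sized fragments were thus stacked around these 3 regions. Around 36621601 on chromosome 17 they numbered 154 in the other Tcf7KO EILP cells, against 25 around 63086801, so that region was not free of stacking either. Whether any of these regions is an accessible site or a pile-up that passed the filter was not tested. The 2 lower regions lay on chromosome 9 at 122557201 to 122557400 (0.571-fold, 0.369 to 0.871) and 63978801 to 63979200 (0.620-fold, 0.433 to 0.880). For ILCP 5 regions were higher and 3 lower, where the median fold over all regions of at least 100 fragments was 1.38 (1.05 for Tcf7KO EILP), a value that lies inside the intervals of 4 of the 5 higher regions. The higher ones were on chromosome 16 at 10975201 to 10975400 (2.06-fold, 1.39 to 3.06), chromosome 11 at 3000401 to 3000600 (1.71-fold, 1.31 to 2.23), chromosome 9 at 3002401 to 3002600 (1.63-fold, 1.25 to 2.12), chromosome 12 at 68160201 to 68160600 (1.61-fold, 1.12 to 2.31) and chromosome 9 at 83452801 to 83453000 (1.58-fold, 1.23 to 2.02). The lower ones were on chromosome 11 at 3057401 to 3057800 (0.568-fold, 0.386 to 0.819), chromosome X at 109484201 to 109484800 (0.601-fold, 0.371 to 0.946) and chromosome 2 at 181665001 to 181665200 (0.617-fold, 0.383 to 0.964). In the shared blocks alone, the folds for Tcf7KO EILP were 6.48 at 36621601 and 1.19 at 63086801 on chromosome 17 and 4.42 at 121307201 on X, and those for ILCP 1.25 at 10975201 on chromosome 16 and 1.04 at 83452801 on chromosome 9, lower than the pooled folds. The intervals are exact conditional binomial ones for counting error, and the regions were picked for the size of their change. Pile-ups were not tested for the ILCP regions either, among them 3002401 on chromosome 9 and 3000401 and 3057401 on chromosome 11.

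The populations differed in sex chromosomes. The Y chromosome held 0.191% of nucleosome-sized fragments in Tcf7KO EILP, 0.00794% in EILP and 0.00643% in ILCP, and the X chromosome held 3.39%, 5.28% and 5.35%. Block medians of the Y share ran from 0.170 to 0.217% in Tcf7KO EILP and reached at most 0.0172% in EILP, so the difference held in each block, shared ones included. Comparisons of Tcf7KO EILP with EILP are therefore also comparisons of cells with and without a Y chromosome. Block medians of EILP were 0.00904 to 0.0172% in the 4 blocks shared with Tcf7KO EILP and 0.00168 to 0.00465% in blocks 4, 5 and 9. Those of ILCP were 0.0126 and 0.0128% in blocks 14 and 15 and 0.00239 to 0.00671% elsewhere. What raised the Y share of these cells in shared blocks was not tested, so folds in shared blocks are not a check free of it. In 10-kb windows of nucleosome-sized fragments, 43 windows were at least 2-fold higher in Tcf7KO EILP in both shared and other blocks, 27 of them on X, and 850 windows on X were lower. Short fragments summed over accessible regions on X were 1.22-fold higher in Tcf7KO EILP than in EILP (1.16 to 1.28), and those in autosomal regions 0.829-fold (0.823 to 0.836). For ILCP these folds were 1.29 (1.22 to 1.36) on X and 1.09 (1.08 to 1.10) on autosomes. The sums on X include the stacked region at 121307201, and no fold was taken by block or without it. The share of short fragments in all regions was not separable from the spread between blocks. Opposite changes of accessibility on X and autosomes are therefore not read from these folds. Between ILCP and EILP 4 of the 10-kb windows were at least 2-fold higher and 19 lower.

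**Figure D5:**
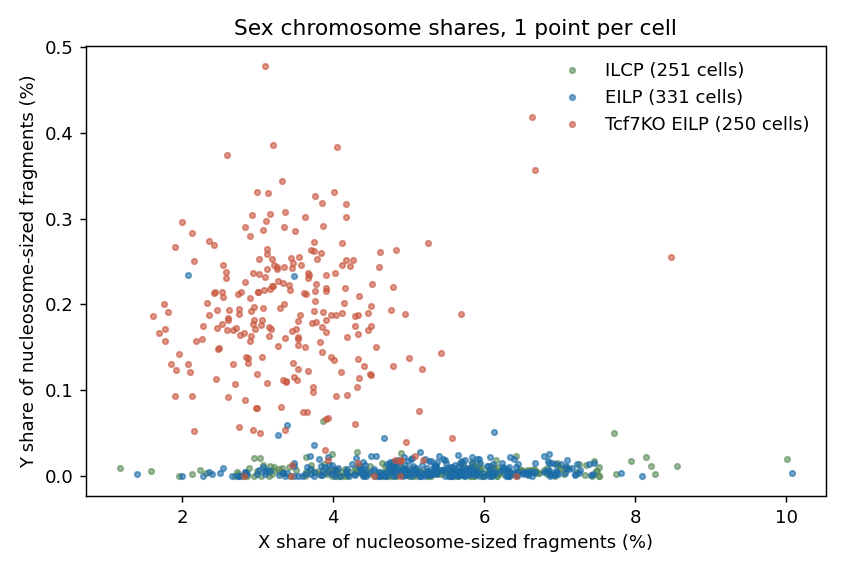
X share (horizontal axis) and Y share (vertical axis) of the nucleosome-sized fragments of each cell, in percent, with 1 point per cell. A Y share of at least 0.05% was reached by 233 of 250 Tcf7KO EILP cells, 4 of 331 EILP cells and 1 ILCP cell, and the 2 highest EILP cells had 0.235 and 0.234%.

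Mean similarity of thinned cells was low, and within a population no higher, or little higher, than between populations. After thinning to 5585 short fragments per cell, the mean cosine similarity over accessible regions was 0.00551 between EILP cells, 0.00491 between Tcf7KO EILP cells and 0.00623 between ILCP cells. It was 0.00504 between EILP and Tcf7KO EILP cells, 0.00552 between EILP and ILCP cells and 0.00514 between Tcf7KO EILP and ILCP cells. Thinning left out 15 EILP, 27 Tcf7KO EILP and 42 ILCP cells. A thinned cell held a median of 112.5 (EILP), 99 (Tcf7KO EILP) and 113 (ILCP) of the 21478 regions compared. Cells with so few regions share some by chance, more so with more regions per cell. The similarity that chance gives was not computed, so these values do not show how alike the cells of the populations were. Pairs from the same block were more alike (0.00628, 0.00553 and 0.00728 for EILP, Tcf7KO EILP and ILCP) than pairs from different blocks (0.00536, 0.00479 and 0.00583), and the standard deviation over pairs of blocks was 0.000703 for EILP, so the populations differed by about as much as blocks did.

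Clustering of all 832 cells gave 8 clusters, which are given by number because no gene markers could be applied. Each of clusters 1 to 7 held cells of the 3 populations. Cluster 1 held 22.4% of EILP, 19.6% of Tcf7KO EILP and 9.16% of ILCP cells. Cluster 8 held 38 Tcf7KO EILP cells (15.2%, exact 95% interval 11 to 20.3%), 7 EILP cells (2.11%, 0.854 to 4.31%) and 1 ILCP cell (0.398%, 0.0101 to 2.20%), and its cells had a median of 39679 short fragments against 15276 over all cells. Clustering on autosomes alone, an alternative added after seeing the data, gave no such cluster, and its cluster with the highest share of Tcf7KO EILP relative to EILP (cluster 7) held 16.4% of Tcf7KO EILP, 9.06% of EILP and 5.58% of ILCP cells. Nearest neighbours were of the same population in 42.6% of cases, where 34.0% are given by chance, and of the same block in 15.2%, where 7.93% are given by chance.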

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

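All tests of this part were chosen after the results were seen.

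Sex-linked signal in data outside the main comparisons flagged 5 values. The Y share of nucleosome-sized fragments was 0.191% in Tcf7KO EILP, and the 4 Y-linked genes summed to 112 CPM in library KO1 and 75.1 CPM in KO3, above the libraries labelled WT. Single EILP cells in blocks 11 and 15 had Y shares of 0.235% (6818 fragments) and 0.234% (76175 fragments), above the other EILP cells.

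In Tcf7KO EILP 93.2% of cells had a Y share of at least 0.05%, which is consistent with male donors of most of these cells, while the X share was 0.641 times that of EILP, above the 0.5 that 1 copy against 2 gives. Windows far higher in this group on autosomes (16 windows, 2.05-fold to 11.7-fold) may hold Y-linked sequence placed on other chromosomes. The 17 Tcf7KO EILP cells with a Y share under 0.05% held 30 fragments there (exact 95% interval 20.2 to 42.8), where the rate of the other Tcf7KO EILP cells gives 97.6 and that of EILP gives 21. These 17 cells were shallow, with a median of 8502 nucleosome-sized fragments against 76093 in the other Tcf7KO EILP cells. A change that comes with the Tcf7 genotype stays open, because the X share of those 17 cells, 4.07%, lay between the 3.37% of the other Tcf7KO EILP cells and the 5.28% of EILP, so that their own genotype is in doubt, and 13 of them came from block 7. The 2 EILP cells had X shares of 2.08% and 3.48%, below the 5.28% of EILP and below or near the 3.39% of Tcf7KO EILP, and a wrong label for them stays open.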

How the results depend on the processing

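Settings called added here, and the tests on them, were chosen after seeing the data. The count of 22 genes between the libraries labelled KO and WT was 52 with a pseudocount of 0.1 (46 higher, 6 lower, 16 shared) and 30 with no filter (20 shared). It was 0 with each library left out (lowest 0, highest 0) and 0 with the replicate number as a replicate block (635 genes at an unadjusted p under 0.05). Among added settings limma gave 0 with a trend (802 unadjusted), 5 after quantile normalisation (2 higher, 3 lower), 0 with the genes detected as a covariate (649 unadjusted) and 0 among libraries without Y-linked transcripts (8.92% of genes unadjusted). The replicate numbers do not pair the libraries (correlations of deviations -0.0317 to 0.0101, 2 of 6 libraries closest to their own number), and the block changed no list call. The genes named by rule and Spib, S100a8 and Ccr6 kept their direction in the 13 alternatives, Tcf7 excepted, whose log2 fold change ran from -0.04 to 0.20, and each called one lost its call in 10 to 12 of them. In camera with the preset correlation the myeloid list passed in each alternative with at least 2 libraries per group (adjusted p 1.63e-06 to 0.00293), and the dendritic cell list in each of these except without WT3 (9.24e-05 to 0.0762 with a library left out; the cause was not tested). With an estimated correlation neither passed (adjusted p = 0.241 for both).

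The share of regions at least 2-fold apart moved for Tcf7KO EILP and ILCP against EILP to 36.8% and 34.2% with stricter regions, 40.1% and 41.4% scaled to fragments in regions, 53.2% and 53.4% after thinning, 51.7% and 42.5% in shared blocks, and 62.9% and 60.8% at 1.5-fold, beside EILP sets at 37.4% and 37.6%, 40.7% and 40.7%, 53.7% and 53.7%, 54.1% and 43.3%, and 62.4% and 62.4%. Among regions under 50 fragments (added) Tcf7KO EILP gave 42.4% and ILCP 40.4%, beside EILP sets at 41.7% and 41.8%. On autosomes only (added) they gave 41.8% and 39.8%, beside 41.2% and 41.3%. Spacing in EILP, Tcf7KO EILP and ILCP was 190.3, 193.8 and 192.5 bp after thinning. With pile-ups kept (added) the slopes were 197.9, 184.08 and 198.6 bp over 8, 8 and 9 peaks in place of 6, and are not read as spacing. Centre over flank was 0.747, 0.723 and 0.729 with fragments of 150 to 170 bp and 0.857, 0.835 and 0.839 with all regions (added). At the 25th percentile similarity was 0.00903 within EILP, 0.00798 within Tcf7KO EILP, 0.00943 within ILCP, 0.00822 between EILP and Tcf7KO EILP, 0.00887 between EILP and ILCP and 0.00814 between Tcf7KO EILP and ILCP. At resolution 0.5 there were 3 clusters, and neither these nor the 8 on autosomes alone (added) held one like cluster 8. Fewer or more fragments entered by construction in the thinned, shared-block and percentile settings, and for the others the cause was not tested. Counting repeated positions once gave no value, since no file repeats a position. Accessibility of the gene lists and its alternatives were not run, for want of gene coordinates on mm9. The median of 13 fragments per region limits what single regions can show.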

Other observations

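All tests of explanations in this part were chosen after the results were seen.

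Globin transcripts differed between the libraries labelled KO. Hbb-bs, a β-globin gene, stood at 1503 CPM in KO1 and 209.9 CPM in KO3 but at 3.91 CPM in KO2, with 13.2 ± 12.1 CPM in WT (mean ± SD, n = 3). Gata2, a transcription factor of stem, mast and megakaryocyte cells, stood at 0.0197 ± 0.0340 CPM in WT and 11.1 ± 8.64 CPM in KO. The median log2 fold change over all genes was 0.08. It was 0.47 for the 3239 genes with a mean log2 value of 0 to 2 and -0.08 for the 3237 genes at 6 or more.

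The 22 genes and 2 lists called between the libraries labelled KO and WT were set against the 10 splits of the 6 libraries into 2 groups of 3, which are too few for a share under 0.05. For genes, 2 of the 10 splits gave as many, and the highest other, WT1, WT2 and KO3 against the rest, gave 67. Several times the real count, this points to a structure of the samples, and those libraries had 11340 to 11744 genes detected against 12259 to 12909 in the rest. For lists, 3 of the 10 gave as many, with 2 as the highest other. With the genes detected as a covariate the median size of the log2 fold change of the 22 genes went from 4.05 to 3.91 and its median SE from 0.354 to 0.434, so the calls ended with a wider error and little change in size, and breadth of detection, which correlates with the labels (0.532), cannot be told apart from them.

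For the myeloid list, breadth of gene detection stays open. With that covariate its median log2 fold change went from 1.82 to 1.76 and its camera adjusted p was 0.00293 at the preset correlation (1.63e-06 to 0.00293 over its alternatives with at least 2 libraries per group), but the adjusted p was 0.250 with an estimated correlation, and 0.241 without the covariate. The sex of the donors stays open, because the adjusted p of 0.00319 among libraries without Y-linked transcripts rests on 1 library labelled KO. Myeloid progenitors in the sorted cells may also contribute, as Mpo, Elane, Prtn3, Ctsg and Ms4a3 had a median log2 fold change of 1.71 and a median of 286.2 CPM in KO (highest 2552, Mpo). Of these 5 genes 3 are in the myeloid list and 4 reach 10 CPM in WT, the sort on lineage markers, 2B4 and α4β7 was not tested for progenitors, and a change within EILP that comes with the Tcf7 genotype was not tested apart from these.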
